A study of Mus musculus with 3 samples.

How the data were processed

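RNA sequencing was carried out on 3 libraries of sorted group 2 innate lymphoid cells (ILC2s), which are tissue lymphocytes without rearranged antigen receptors that make type 2 cytokines. The series' design text states that the cells came from 3 wild-type mice, and the labels give the strain as C57BL/6. The sort kept cells positive for CD45, CD90.2, CD127 and KLRG1 and excluded cells carrying CD3, CD5, CD8, NK1.1, CD11b, CD11c or B220. Per the labels' protocols, libraries were made with a SMARTer ultra-low-input kit, which amplifies full-length cDNA from few cells, and sequenced by standard Illumina procedures. Such kits do not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The tissue, the time of day of collection, and the age and sex of the mice are not given in the sources used here.

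The deposited table holds raw read counts, as whole numbers per Entrez gene ID, with 1 column per library and no normalization by the authors. Per the submitters' processing notes, CASAVA 1.8.2 and STAR 2.3.0 were used with the mm10 mouse genome build. The counting program, the annotation release and the treatment of reads that map to several places are not given in the sources used here. The table has 27179 gene IDs. Of these, 25275 were matched by ID to the RefSeq gene table of GRCm38.p6, the assembly that mm10 corresponds to, and coordinates are 1-based positions from that table. IDs without a name held 0.242%, 0.215% and 0.186% of the counts of mice 1, 2 and 3. They stayed in the library sizes and in the test of variability. No row was a total or an unassigned class. Of the 405 entries of the gene lists, only Hbb-bt had no row.

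Each library is called mouse 1, 2 or 3 after the sample number in its title, which itself names no mouse. Library totals were 22112425, 17819551 and 26374248 counts for mice 1, 2 and 3. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.132, 0.171 and 0.115 CPM, which are counts scaled to 1000000 counts per library. Reads carried no molecular identifiers, so these limits and all binomial intervals cover counting error only. A chi-square test on genes with at least 10 counts in the pair showed that each pair of libraries differed by far more than sampling noise, with a statistic of 133 to 226 per degree of freedom. No pair thus agreed within sampling noise, as copies of a single library would. The 3 libraries were counted as separate samples because the design text names 3 mice.

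CPM were computed on library sizes scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.03, 0.987 and 0.989. Log values are log2(CPM + 0.5). A gene was called detected when it reached 1 CPM in each of the 3 libraries. CPM were not divided by gene length, and comparisons between genes depend on length in full-length libraries. Values divided by the summed exon length of GENCODE M21, in kb, were computed as an alternative, and all genes of the fixed lists had such a length. The 0.5 was added after this division and weighs more on low values. A lower difference in that setting is therefore not due to length alone. Background was taken from 1500 olfactory, vomeronasal and trace amine receptor genes, whose 95th percentile was 0 CPM in each library.

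The series holds 1 group, so no contrast between conditions was possible. The design fixed before the data were examined therefore has 3 kinds of result. Levels of fixed gene lists and of gene pairs were compared within each library, with the mean and SD over 3 mice. An exact two-sided sign-flip test on 3 libraries cannot give a p below 0.25, so no within-library difference can pass 0.05 in that test. Genes shared by 2 lists were left out of both in a difference. The median of each list was also placed among the medians of 10000 random lists of the same size, drawn from genes with a count. Between-mouse variation was measured with edgeR on the genes that passed filterByExpr (minimum count 10). A quasi-likelihood fit with an intercept only gave each gene's quasi-dispersion, and its ratio to the abundance trend was tested with an upper-tail F test and Benjamini-Hochberg adjustment at 0.05. For lists with at least 5 tested members, the median ratio was compared with 10000 random lists matched on abundance in 20 bins, two-sided. Genes of a list are not independent replicates, so these list tests describe these 3 libraries.

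The variability test was tested on simulated data with 9175 genes. When 1 library of a gene was raised 8-fold, 22 of 100 genes were recovered. With a 64-fold rise 79 of 100 were recovered, with 0 false calls. In the permutation test of lists, 15 changed genes gave p = 0.0002 and 15 unchanged genes gave p = 0.0564.

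Alternatives were library size without TMM, DESeq2 (1.42.0) size factors and dispersion outliers, limma (3.58.1) variances, a robust prior, other minima and pseudocounts, gene length, means in place of medians, and leaving out each mouse. Genes named are members of the fixed lists, the 15 most abundant genes outside mitochondrial and ribosomal protein genes, and the 10 genes with the lowest p in the variability test. Genes of the immunoglobulin loci beyond these, the plasma cell marker set of the closing section and the ribosomal protein genes were chosen after values had been seen. Some members of the fixed lists, and 2 of the gene pairs planned, are not reported here; they stay in the counts and medians of their lists.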

Results

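The transcriptomes of ILC2s sorted from 3 wild-type mice were profiled by RNA sequencing, within a study whose title concerns the circadian clock in group 3 innate lymphoid cells (ILC3s) of the gut. The libraries held 17819551 to 26374248 counts. Between 12247 and 13471 genes had at least 1 count, and 8461 genes were detected at 1 CPM in each of the 3 mice. Pearson's correlation of log2 CPM between libraries, across 15092 genes, was 0.924 to 0.931. Genes are not independent replicates, and the coefficients describe agreement only. The common biological coefficient of variation between the mice was 45.1%. With 1 library per mouse, this and each spread between mice below also hold variation from the sort and the amplification. All values below are mean CPM ± SD over 3 mice unless stated otherwise.

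The most abundant transcripts by mean outside the mitochondrial and ribosomal protein genes included B2m (24827 ± 4363), the invariant chain of class I histocompatibility molecules, and Sub1 (23938 ± 8273). Immunoglobulin Igkc (18997 ± 14693) and Jchain (12597 ± 6555), the joining chain of secreted IgA and IgM, were also among the 15 highest, but unevenly. Igkc had 4822, 18010 and 34158 CPM in mice 1, 2 and 3 and Jchain 5527, 13790 and 18473, and in mouse 1 both lay below the other 13 genes. Id2 (7782 ± 1497), the regulator needed by all innate lymphoid cells, Csf2 (7198 ± 2199), which encodes GM-CSF, Crem (6354 ± 760) and Il2rg (5527 ± 813), the common cytokine receptor chain, were also among the 15 highest. The remaining 7 were Samsn1, Hilpda, Cnbp, Itm2b, Emb, Ly6e and Srgn. Mitochondrial transcripts made up 1.77% to 3.01% of counts.

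The first comparison asked whether the libraries carried the transcripts of the sorted phenotype. All 4 genes of the positive sorting antibodies were detected. Klrg1 had 1304 ± 234 CPM, Il7r (CD127) 1058 ± 195, Ptprc (CD45) 468 ± 90.5 and Thy1 (CD90) 28.2 ± 8.83. Of the 9 genes of the excluded antibodies, 3 were detected, and all encode CD3 chains. Cd3g reached 321 ± 60.4 CPM, whereas Cd3e had 6.92 ± 3.04 and Cd3d 1.97 ± 1.03. Cd8a, Cd8b1, Itgam (CD11b) and Itgax (CD11c) were each below 0.1 CPM on average, and Cd5 had 0.658 ± 1.09. Klrb1c (NK1.1) was uneven, with 0.0441, 6.54 and 2.95 CPM in mice 1, 2 and 3. B220 is an isoform of the Ptprc product and cannot be read from gene counts. At a minimum of 5 CPM, only Cd3g of the 9 excluded genes remained. Xist was present at 40.9 ± 7.32 CPM, and Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in every library.

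The second comparison set the ILC2 programme beside those of other lineages. Of 28 ILC2 core genes, 27 were detected and 18 exceeded 100 CPM on average. The lineage regulators Gata3 (438 ± 76.4) and Rora (417 ± 115) were present with the receptors for the alarmins IL-33 (Il1rl1, 136 ± 52.9) and IL-25 (Il17rb, 513 ± 83.3). The receptor for TSLP, Crlf2, was far lower at 6.33 ± 0.945. Icos (1667 ± 158), Ccr8 (1754 ± 439), Hs3st1 (3022 ± 877) and Arg1 (794 ± 93.8), which encodes arginase-1, were high, as was Calca (4603 ± 903), the gene of calcitonin and CGRP. Bcl11b (8.38 ± 1.68), Gfi1 (6.03 ± 1.96) and Tcf7 (12.5 ± 8.61) were among the lowest detected members. Ptgdr2, which encodes the prostaglandin D2 receptor CRTH2, had no counts in any mouse. The median of the ILC2 core list lay above all 10000 random lists of the same size.

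The median of the ILC2 core list was higher than that of each of the 10 other lineage lists in 3 of 3 mice. Some lists hold genes of the sorting antibodies, such as Klrg1 (ILC2 core), Cd3e (T cell), Itgam (myeloid) and Klrb1c (NK cell and ILC1). The sort itself may thus have set part of these differences. The mean log2 difference was 4.48 ± 1.00 (SD, n = 3) against the ILC3 list, 4.04 ± 1.10 against B and plasma cell genes (4.64 ± 0.51 without mouse 3), 6.81 ± 0.12 against myeloid genes and 6.96 ± 0.39 against T cell genes. No fold is given against NK cell and ILC1 genes, whose median in mouse 1 lay below the level that a count of 0 allows. In each case the exact sign-flip p was 0.25, the smallest that 3 libraries allow. Division by exon length left the direction in place for all 10 lists but lowered the difference from the B and plasma cell list to 1.87 ± 0.78, from the ILC3 list to 2.41 ± 0.64, from the myeloid list to 4.56 ± 0.13 and from the T cell list to 5.54 ± 0.58. Restriction to list members that reached 1 CPM in some library gave 1.32 ± 0.33, 3.33 ± 0.88, 4.64 ± 0.73 and 5.60 ± 0.44 for these 4 lists. Means of list members in place of medians gave 3.04, 3.57, 4.82 and 4.94. The lists of gut epithelium (1 of 15 detected), lung epithelium (0 of 7) and mast cells, basophils and eosinophils (3 of 12) had a median of 0 CPM, and no fold is given against them. Epcam (19.7 ± 13.9) was the detected member of the gut epithelial list. Of the stromal and endothelial list 3 of 10 members were detected, and of the erythroid list 0 of 4.

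**Figure D1:**
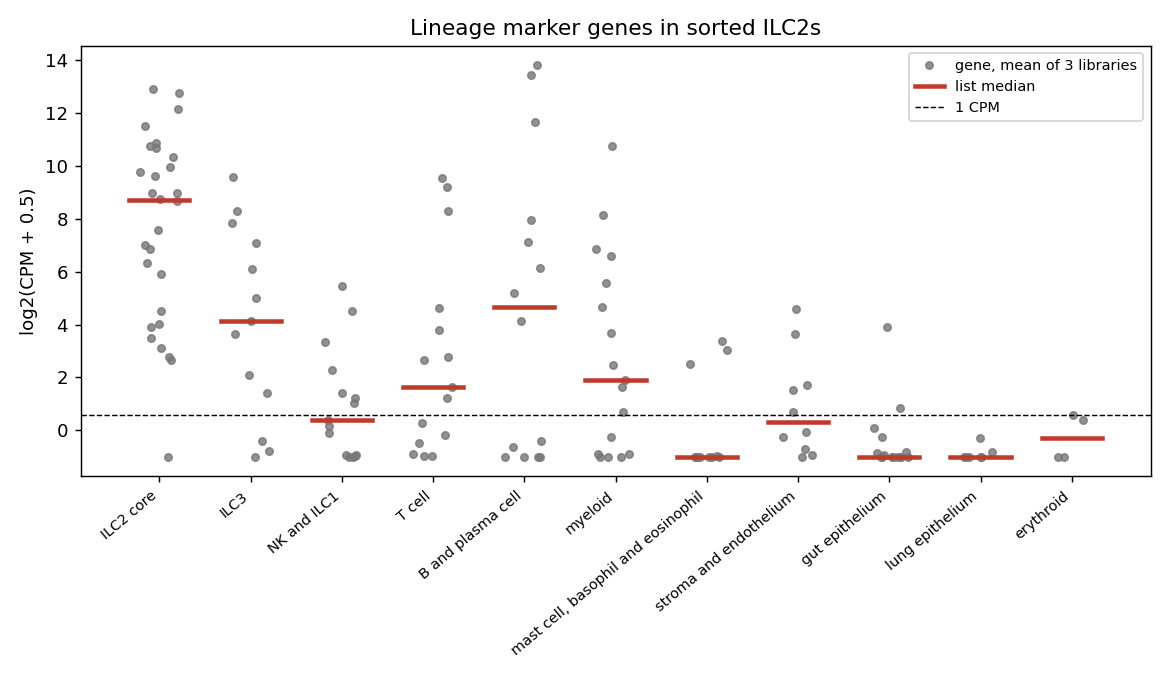
Expression of marker genes for 11 lineages in sorted ILC2s. Each point is the mean log2(CPM + 0.5) of 1 gene over 3 libraries, horizontal bars are list medians, and the dashed line marks 1 CPM; the ILC2 core list, with 27 of 28 genes detected, has the highest median.

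Members of other lineages' lists were nevertheless present at levels of the ILC2 core genes. Among T cell genes 8 of 15 were detected, led by the T cell receptor beta constant regions Trbc1 (758 ± 23.2) and Trbc2 (596 ± 33.2), near-identical paralogues whose reads the counting could divide. The alpha constant region Trac had 13.5 ± 1.04 CPM. Cd4 had a single count across the libraries and Foxp3 0.283 ± 0.453 CPM. Among myeloid genes 10 of 17 were detected, led by the class II histocompatibility chaperone Cd74 (1781 ± 498). It was followed by Cst3 (283 ± 25.8), H2-Ab1 (117 ± 26.7) and H2-Aa (98.8 ± 24.0). Adgre1, S100a8 and S100a9 had no counts. Among B and plasma cell genes 8 of 14 were detected. They were Igkc, Jchain, Igha (4391 ± 4332), Ighm (254 ± 75.2), Iglc2 (88.1 ± 57.7), Cd79a (21.3 ± 17.7), Cd79b (141 ± 12.8) and Mzb1 (44.1 ± 35.8). Igha was highest in mouse 3, with 1742, 2040 and 9391 CPM in mice 1, 2 and 3. The B cell genes Ms4a1 and Pax5 had 0 counts in each library.

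The type 2 programme was then compared with the type 3 and type 1 programmes within the same libraries. All 6 type 2 genes were detected. Csf2 was followed by Il5 (1930 ± 545), the eosinophil growth factor, Areg (993 ± 62.0), which encodes amphiregulin, and Il4 (952 ± 491). Il13, a defining ILC2 cytokine, had only 24.1 ± 10.9 CPM and Il9 7.48 ± 6.26. The 3 type 3 cytokine genes were detected at low levels, Il17f at 39.7 ± 29.2, Il22 at 19.7 ± 12.1 and Il17a at 15.1 ± 9.99. Ifng had 4.77 ± 2.52 CPM. Tbx21 and Eomes, the regulators of ILC1s and NK cells, each had a single count in mouse 2.

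Gata3 lies on chromosome 2 (9857078 to 9887953, mm10). Gata3 had 525, 409 and 381 CPM in mice 1, 2 and 3. Il13 exceeded Il22 in 2 of 3 mice, by 0.38 ± 1.07 on the log2 scale (SD, n = 3), with an exact sign-flip p of 0.5; without mouse 3 the difference was 0.99 ± 0.17. Il5 exceeded Il17a in 3 of 3 mice by 7.25 ± 1.68 (6.27 ± 0.14 without mouse 1), and Il13 exceeded Ifng by 2.25 ± 0.94, each with the smallest possible exact p of 0.25. Gata3 exceeded Tbx21 and Il1rl1 exceeded Il23r in 3 of 3 mice, also at p = 0.25 in the exact test, and no fold is given because Tbx21 and Il23r lay at or near the floor. Genes of the ILC3 list were divided. Ltb (771 ± 135), Kit (244 ± 103), Tnfsf11 (139 ± 24.0) and Ahr (70.0 ± 17.9) were detected, whereas the IL-23 receptor gene Il23r (0.0863 ± 0.0853) and Il1r1 (0.271 ± 0.160) were below 1 CPM and Ccr6 had no counts.

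**Figure D2:**
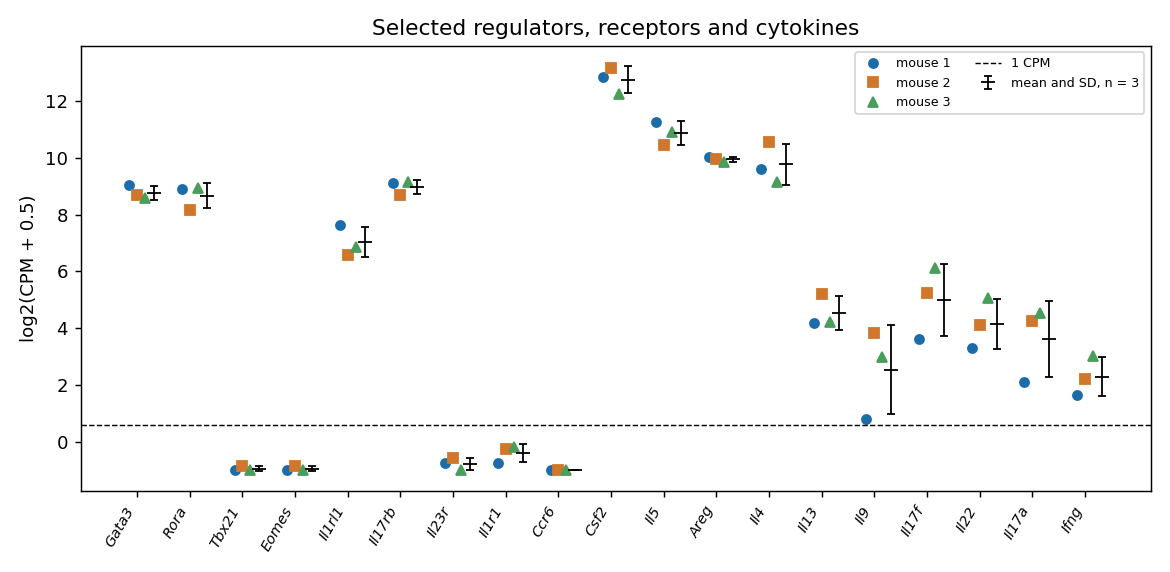
Selected regulators, receptors and cytokines of the 3 innate lymphoid programmes. Symbols give log2(CPM + 0.5) per mouse, black bars the mean and SD of the log values (n = 3), and the dashed line 1 CPM; Csf2, Il5, Areg and Il4 lie above the other cytokine genes, and Il23r, Il1r1 and Ccr6 lie below the line.

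The third comparison concerned the circadian clock, the subject named by the series title. Of 28 clock genes in the fixed lists 19 were detected at 1 CPM in every mouse, and none lacked counts altogether. Of the nuclear receptors, Rora was the most abundant of those named here, with Nr1d2 (REV-ERBβ) at 129 ± 33.9 and Nr1d1 (REV-ERBα) at 1.82 ± 0.656. The positive limb was represented by Arntl (BMAL1, 27.9 ± 10.9; chromosome 7, 113178471 to 113314126) and Clock (16.0 ± 4.90). Npas2 was uneven, with 1.19, 0 and 3.30 CPM in mice 1, 2 and 3. In the negative limb, Bhlhe40 (DEC1) reached 687 ± 144 CPM and Per1 18.1 ± 1.66, while Cry1 had 3.82 ± 1.20. Cry2, Ciart, Per2, Per3 and Bhlhe41 did not reach 1 CPM in all mice. Among the PAR bZIP output genes and their antagonist, Nfil3 (121 ± 47.1), which is also a regulator of innate lymphoid development, and Hlf (29.9 ± 9.36) were well above Dbp (2.82 ± 0.511) and Tef (1.88 ± 2.18). Of the kinases and ubiquitin ligases 7 of 8 were detected, among them Csnk1d (45.0 ± 7.89) and Fbxl21 (151 ± 31.2).

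Arntl exceeded Nr1d1 in 3 of 3 mice, by 3.57 ± 1.03 on the log2 scale (SD, n = 3), and exceeded Dbp by 3.02 ± 0.60. Nfil3 exceeded Dbp by 5.13 ± 0.66. Clock exceeded Npas2 in 3 of 3 mice, and no fold is given because Npas2 had 0 counts in mouse 2. The exact sign-flip p was 0.25 for each, the smallest possible. Division by exon length kept these directions but lowered the first 2 differences to 1.90 and 1.48. The 19 detected clock genes had a median coefficient of variation between mice of 27.7%, against 25.8% for random genes matched on abundance, which placed them at the 65.3th percentile of 10000 draws. No time of collection is labelled, so the levels cannot be placed in a daily cycle.

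**Figure D3:**
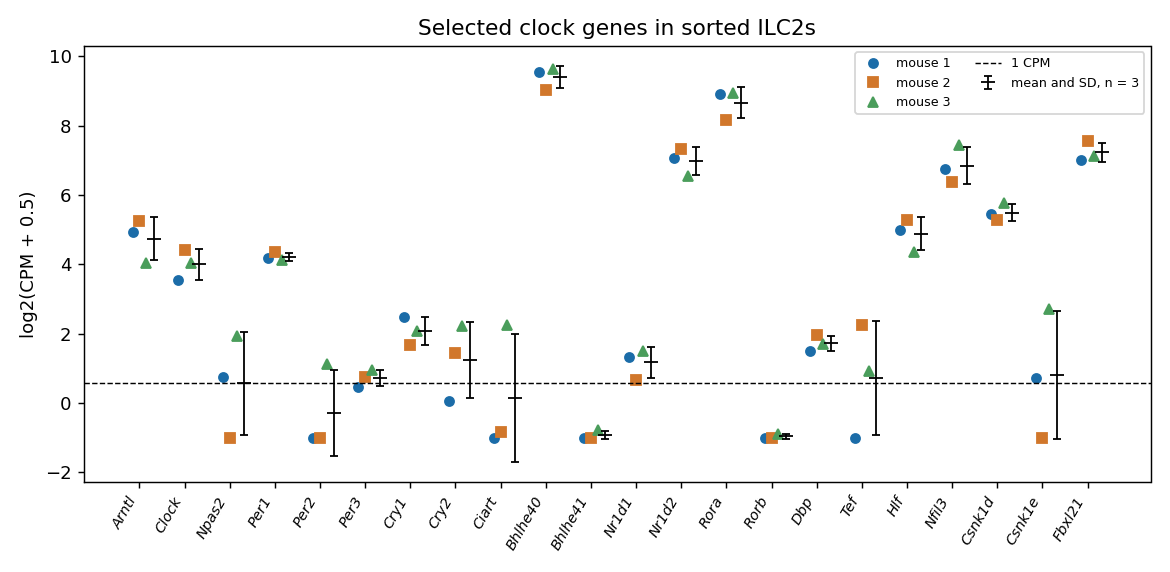
Expression of selected clock genes in sorted ILC2s. Symbols give log2(CPM + 0.5) per mouse, black bars the mean and SD of the log values (n = 3), and the dashed line 1 CPM; Bhlhe40 and Rora are the highest of the genes shown, and Bhlhe41 in each mouse and Per2 in mice 1 and 2 lie at the floor.

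The last comparison asked which genes differed most between the mice. Of 9175 genes tested, 17 were more variable than genes of their abundance at an adjusted p below 0.05 (edgeR quasi-dispersion F test, Benjamini-Hochberg). Of these, 16 were immunoglobulin segments, and the other was Gzma, which encodes granzyme A. At an unadjusted p below 0.05 there were 416 genes, where chance alone gives 459. The 10 genes with the lowest p were Igkv4-57-1, Igkv6-23, Igkv8-21, Igkv10-96, Igkv12-44, Igkv14-111, Igkv1-110, Igkj5, Ighv1-9 and Igkj1. Igkv4-57-1 had 0.926, 2.10 and 1770 CPM in mice 1, 2 and 3. Igkv10-96 had 1.46, 1650 and 10.4 CPM, and Ighv1-9 had 314, 233 and 0.460 CPM. V segments are a multigene family, so reads may have been divided between similar members. The highest value was in mouse 3 for 11 of the 16 segments, in mouse 2 for 4 and in mouse 1 for 1.

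Gzma had 7.19, 229 and 48.2 CPM in mice 1, 2 and 3 (adjusted p = 0.00375). The call was lost without mouse 2 (adjusted p = 0.589), without a filter (0.151), among genes at a mean of 5 CPM or more (0.0539) and with a robust prior (0.987). Of the other NK cell and ILC1 genes, Prf1 (0, 5.63 and 0.230 CPM), Klrb1c and Xcl1 (0, 1.36 and 0.384) were also lowest in mouse 1 and highest in mouse 2. Gzmb (30.0, 14.0 and 27.3) was lowest in mouse 2, Ncr1 (1.24, 2.10 and 3.57) was highest in mouse 3, and Klra4 and Klra8 had no counts. Among the 230 tested genes of the fixed lists it was the only one to pass over all genes tested. Adjusted over the list alone, 4 genes passed, Gzma, Igha, Dusp1 and Hsph1. Dusp1, an immediate early phosphatase gene, had 477, 203 and 975 CPM, and Hsph1, a heat shock gene, had 0.926, 42.7 and 18.6 CPM. Immunoglobulin transcripts together made up 1.04% of counts in mouse 1 (95% Wilson interval 1.04% to 1.05%), 3.89% in mouse 2 (3.88% to 3.90%) and 7.81% in mouse 3 (7.80% to 7.82%). When the immunoglobulin genes were left out, 1 gene passed, and it was Gzma.

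Of 20 gene lists tested for variability, only the B and plasma cell list stood apart from random lists matched on abundance, with a median log2 ratio to the trend of 2.60 (permutation p = 0.0002, the smallest the draws can give; adjusted p = 0.004 over 20 lists). The ILC3 list (0.99), the innate lymphoid transcription factors (0.69) and the immediate early and heat shock genes (0.66) each had an adjusted p of 0.059. The ILC2 core list (-0.23, adjusted p = 0.858) was not distinguishable from random lists. The call for the B and plasma cell list was lost without mouse 1 (adjusted p = 0.824) and without mouse 3 (adjusted p = 0.827), where the type 2 cytokine list passed instead. Leaving out the immunoglobulin genes, an alternative added after the data were seen, left too few tested members of that list, and 4 others then passed: the ILC3, type 2 cytokine, innate lymphoid transcription factor and immediate early lists. Without mouse 1, 31 genes passed, of which 11 were among the 17. With a robust prior edgeR called 0 genes, with 408 at an unadjusted p below 0.05. DESeq2 marked 24 dispersion outliers and limma called the same 17 genes.

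**Figure D4:**
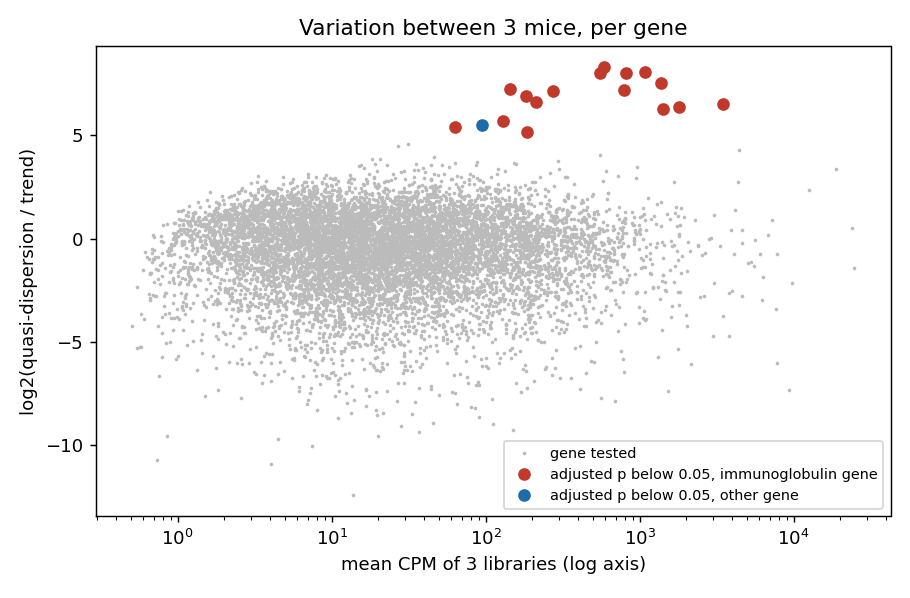
Between-mouse variation per gene. The x axis is mean CPM over 3 libraries on a log scale and the y axis is log2 of a gene's quasi-dispersion over the abundance trend; grey points are the 9175 genes tested and large points the 17 with adjusted p below 0.05, of which 16 are immunoglobulin segments (red) and 1 is Gzma (blue).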

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

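The setting without immunoglobulin genes was chosen after the data were seen, and all other settings before. No paired analysis was possible because the series has 1 group. Library size without TMM and DESeq2 size factors left every count of the report within 1.5 times its value. In all, 60 comparisons of main results with an alternative showed no shift beyond that limit or beyond 1 SD, against 11 that did. Among the other comparisons 309 held, 35 moved and 5 list ranks became more extreme. Counts were compared by size only: without a filter 22 genes passed, of which 13 were among the 17. Without each mouse in turn, 8762 to 9068 genes were detected, the log2 difference between the ILC2 core and ILC3 lists was 3.92 to 4.87, the count of more variable genes was 13 to 31 (highest without mouse 1), and 0 to 3 lists passed the variability test (0 without mouse 1, 3 without mouse 2, and without mouse 3 the type 2 cytokine list in place of the B and plasma cell list). With 2 libraries 1 residual degree of freedom remains. Without mouse 3, all 5 regulator and cytokine pairs reported kept 1 direction, including Il13 over Il22. Division by exon length, with 0.5 added afterwards, lowered the difference between the ILC2 core and ILC3 lists from 4.48 to 2.41. It lowered that from B and plasma cell genes to 1.87. Restriction to list members at 1 CPM in some library gave 3.33 for the ILC3 difference and lowered that from B and plasma cell genes from 4.04 to 1.32, because members at the floor were removed. That setting left no member of the lung epithelial list. A minimum of 5 CPM left 1 excluded sorting marker in place of 3 and 6417 detected genes. Without a filter on low counts the common coefficient of variation was 0.890 in place of 0.451. The count of more variable genes was 17 in the report, 30 among genes at a mean of 5 CPM or more, 22 without a filter, 0 with a robust prior and 1 without immunoglobulin genes, where 4 lists passed in place of 1. Why the robust prior ended the calls was not tested. Depth limits statements on genes with 0 counts, such as Ptgdr2, to the 0.115 to 0.171 CPM that such a count allows. It does not account for the uneven values of Per2, Npas2 and Tef, since Tef had 0, 75 and 36 counts in mice 1, 2 and 3, and the cause was not tested.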

Other observations

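The test of plasma cell genes between mice 2 and 1 was chosen after those values were seen; the other tests below were written down before their results, although the levels of Igkc, of the housekeeping genes and of the plasma cell genes Mzb1 and Cd79a had been seen. Several groups of receptors not described above were present in the ILC2s. The receptor component Ramp3 (747 ± 167 CPM, SD, n = 3) and its relative Ramp1 (108 ± 32.7) far exceeded their partner Calcrl (12.7 ± 2.60), which with Ramp1 forms the CGRP receptor. The neuromedin U receptor gene Nmur1 had 92.2 ± 56.5 CPM, the leukotriene receptor gene Cysltr1 141 ± 42.2 and the VIP receptor gene Vipr2 23.1 ± 6.31, while Vipr1 had no counts. The glucocorticoid receptor gene Nr3c1 had 676 ± 152 CPM. Of 21 homing and chemokine receptor genes 12 were detected, led by Cxcr6 (4130 ± 736), Ccr8 and Cd69 (1276 ± 203), with S1pr1 at 1.18 ± 0.306. Ccr9, the gut homing receptor, was present at 35.2 ± 27.5 CPM.

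Of 23 immediate early and heat shock genes 17 were detected, and the median of this list lay at the 99.7th percentile of random lists of detected genes. Junb had 960 ± 552 CPM, Dusp1 552 ± 391, Fos 329 ± 117 and Nr4a1 216 ± 50.3. Of 16 cell cycle genes 10 were detected, but Mki67 had 3.64 ± 3.16 CPM and Top2a 6.31 ± 7.35. Of 16 lipid and amino acid metabolism genes 13 were detected, with Dgat1 at 664 ± 111, Arg1 at 794 ± 93.8 and Pparg at 117 ± 12.5. Among the remaining cytokines Il6 (453 ± 153) and Il2 (110 ± 24.7) were present and Il10 (0.0782 ± 0.0348) was not detected. Of 16 interferon-stimulated genes 12 were detected, with Rtp4 at 225 ± 108, while Ifit2 and Mx1 had no counts.

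Immunoglobulin transcripts were abundant and differed between the mice. Summed kappa V segments were higher in mouse 3 than in mouse 1 by 3.27 on the log2 scale, against 2.83 for Igkc, which argues against unrearranged constant-region transcripts of the ILC2s as the source. In mouse 1 a single segment, Igkv1-117, held 92.6% of kappa V counts (95% Wilson interval 92.3% to 92.8%), while Igkv11-125 held 42.1% in mouse 2 (41.9% to 42.3%) and Igkv6-15 29.7% in mouse 3 (29.6% to 29.8%). Plasma cells carried through the sort may be a source of the difference between mice 3 and 1, but that test stayed open. Of 8 plasma cell genes that reached 1 CPM, 7 were higher in mouse 3 than in mouse 1. Their median log2 ratio was 1.25 (quartiles 0.61 and 1.92), below the 1.41 set in advance as support. The constant added to CPM before taking logs shrinks the ratios of low genes but hardly changes that of Igkc, from which the 1.41 was set. Pou2af1, for example, had 0.662 and 1.61 CPM in mice 1 and 3 and entered with a log2 ratio of 0.861. The shortfall may thus come from the constant, so it does not count against plasma cells. Jchain was left out of this set, and it had 5527, 13790 and 18473 CPM in mice 1, 2 and 3, the order of Igkc. Between mice 2 and 1 the same 8 genes had a median log2 ratio of 0.0480 (quartiles -0.568 and 0.228), against 1.90 for Igkc. These genes as a set thus did not rise with Igkc. Several were low, such as Pou2af1 (0.662 and 0 CPM in mice 1 and 2) and Tnfrsf13b (3.97 and 1.14), and Jchain rose. Whether plasma cells were the source of that difference therefore stays open. Mzb1 had 22.6, 24.4 and 85.4 CPM in mice 1, 2 and 3 and Cd79a 10.2, 12.0 and 41.7, while Tent5c (0.0441, 8.36 and 21.5) went with Igkc. The sort required CD90.2, CD127 and KLRG1, which would be expected to remove plasma cells, while its B220 gate need not. Free immunoglobulin RNA was not tested.

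Some housekeeping genes had few counts, with Gapdh at 16.9 ± 9.74 CPM, Pgk1 at 6.96 ± 1.44 and Tuba1b at 0. Reads shared with near-identical copies, if they were dropped in counting, are a candidate explanation. Across 94 ribosomal protein and housekeeping genes, the share of 50-base windows found in no other gene's transcripts correlated with mean CPM (Spearman's rho 0.345, permutation p = 0.00063, adjusted p = 0.00126 over 2 relations; Pearson's r with log2 CPM 0.302; rho 0.366 without the 2 genes farthest from the median). The 33 genes with under 50% unique windows had a median of 16.9 CPM against 104 for the other 61. Exon length showed a rho of 0.0736 (permutation p = 0.480), which does not decide. No biological explanation was tested, genes are not independent replicates, and a unique sequence did not go with many counts in every gene: Rpl39 had 83.8% unique windows and 2.74 CPM.

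The type 3 cytokine genes were lowest in mouse 1, with Il17f at 11.8, 37.4 and 70.0 CPM in mice 1, 2 and 3. The share of immunoglobulin transcripts was likewise lowest in mouse 1 and highest in mouse 3, and whether the values are linked was not tested.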
